A study of Mus musculus with 4 samples.

How the data were processed

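Single-cell transcriptomes were made from 4 orthotopic MT4788 mammary tumours of FVB mice, 1 per treatment, collected on day 4 and enriched with CD45 beads; per the labels, over 90% of the cells were of the CD45-positive, CD31-negative and EpCam-negative kind and 10000 cells were loaded per condition on the 10x Genomics 3' platform. The deposited matrices hold raw UMI counts per gene and cell barcode, without normalization, made by the authors with Cell Ranger 3.1.0 per the file headers, and builds mm10 and GRCm38 are named per the submitters' processing notes. Each matrix has 27998 features and as many columns as called barcodes. Aligner settings, the annotation release and any later filter are not given in the sources used here. Gene positions are from GENCODE vM21, matched by Ensembl ID.

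Control, phenformin, poly I:C and combination held 7309, 6539, 7668 and 9303 barcodes. Cells with at least 200 genes and under 20% mitochondrial UMIs were kept, which left 6095, 5453, 6619 and 8268. Scrublet (scanpy 1.11.5, expected rate 6%) called 125, 98, 1 and 3 doublets, which were removed; the calls in both poly I:C-treated libraries, at 0.02% and 0.04% of cells, are so few that the method has not worked there, and no further doublet removal was made for the values in the report. The 5970, 5355, 6618 and 8265 cells used held 55318241, 59121593, 76038874 and 71260253 UMIs. Depth was lowest in neutrophil-like cells, whose sums of 487499 to 837394 UMIs per library leave wide intervals for genes of few counts; all intervals are at the 95% level.

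Libraries were clustered together without integration. Counts were scaled to 10000 per cell and logged, 2000 variable genes were taken after leaving out mitochondrial genes, ribosomal protein genes and the genes of the treatment response lists, and 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2, igraph 0.11.9) gave 32 clusters. Clusters were named from 19 marker sets, with at least 3 markers that were at least 2-fold higher than the mean of the clusters of other classes and found in 5% or more of the cluster's cells. Clusters whose 10 leading genes held more markers of another class, or whose UMI counts were low without a leading marker, were left unnamed, and 26 were named. A cluster with a median doublet score over 0.12 was left unnamed as well, and these limits on naming were set after the data were seen. Of the marker and list symbols 11 are absent from the features (Trac, Trbc2, Trdc, Tcrg-C1, Trdv4, Ighm, Ighd, Mx2, Ifi209, Ifi213 and Acod1) and were left out. Neutrophil-like cells were clustered again (10 components, resolution 0.3), and sub-clusters with a median UMI count over 2 times that of the class were called mixed; this step, its settings and the comparison of tumour epithelial-like cells were chosen after the data were seen.

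With 1 library per treatment no test between treatments was made, and cells were not used as replicates. Shares have exact binomial (Clopper-Pearson) intervals. Counts were summed over the cells of a class and scaled to CPM (counts per 1e6) of that sum, with exact Poisson intervals, and ratios of 2 libraries have the exact interval that is conditional on their total. Where a library had no UMI, 3 counts served as the floor for a bound. The 5 comparisons were phenformin, poly I:C and the combination over control, and the combination over poly I:C and over phenformin; the 2 by 2 layout added the combination beyond the sum of the single treatments. Of 34 gene lists, the median log2 ratio with a pseudocount of 5 CPM was taken over members with at least 20 CPM in 1 library, for lists with 4 or more such members. Its percentile among 10000 random lists matched on expression in 20 bins is given as a description of these libraries. Members counted as higher or lower differ at least 1.5-fold with an interval that leaves out 1. Lists, markers, comparisons and the rule for naming genes were fixed before the data were examined, as were 15 of the alternatives below.

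Genes compared had at least 50 CPM and at least 30 UMIs in the higher library. Named were the 10 highest and 10 lowest by log2 ratio in neutrophil-like cells and the 5 highest and 5 lowest in other classes, up to 4 members of a list with the largest log2 ratio, a fixed set of oxidase, effector and interferon genes in neutrophil-like cells, and the 5 highest and 5 lowest beyond the single treatments. Gene models named by number, immunoglobulin and T cell receptor segments, globins and ribosomal protein genes were left out of this ranking. Some genes that this rule names are not reported here. Genes that report on mixed droplets (Cd3, Apoe, S100a8 and S100a9) were added after their values were seen.

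These 15 alternatives changed 1 choice each: stricter cell filters (500 genes, 10% mitochondrial), no doublet removal, all variable genes, Leiden resolution 0.5 and 2, each library on its own, TMM scaling (edgeR 4.0.16, R 4.3.3), the mean over cells, cells thinned to 1000 UMIs, pseudocounts of 1 and 20 CPM, no limit and 100 CPM for list members, no clusters held over 60% by 1 library, and 20 CPM for compared genes. A further 7 were added after the data were seen, among them clustering without 785 marker, list and leading genes. List medians have counting intervals from 1000 Poisson draws of the counts.

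The ratio step was tested on simulated data, in which 200 genes of neutrophil-like depth were set apart by a known fold, a list of 30 genes was set 1.5-fold apart and the others were left equal. For phenformin, poly I:C and the combination over control, and the combination over poly I:C and over phenformin, 1923, 2155, 2228, 2155 and 1923 genes were in the step. Genes set 2-fold higher were called in 96%, 100%, 98%, 98% and 100% of cases, those set to 0.5-fold in 86%, 88%, 92%, 90% and 92%, and those set 4-fold or 0.25-fold in 100%. Of unchanged genes 1.65%, 1.35%, 1%, 1.4% and 1.3% were called, and 95.5%, 95.5%, 96%, 96.5% and 96.5% of intervals held the fold set. Each summed count was drawn from a Poisson distribution at a fixed library size, so intervals that assume such counts must hold near their set level. Counts gathered in few cells and shifts in composition were not simulated, so these are not error rates of the real data. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.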

Results

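Gene expression was measured with droplet-based 3' RNA sequencing in cells enriched for CD45 from MT4788 mammary tumours, grown orthotopically in FVB mice and collected on day 4. The 4 libraries form a 2 by 2 layout: saline with PBS (control), saline with phenformin (phenformin), poly I:C with PBS (poly I:C) and poly I:C with phenformin (combination). Poly I:C is a synthetic double-stranded RNA that is sensed by Toll-like receptor 3 and by cytosolic RNA sensors. Phenformin is a biguanide that inhibits complex I of the respiratory chain. Control, phenformin, poly I:C and combination held 7309, 6539, 7668 and 9303 barcodes and 59071838, 62744050, 77488625 and 72704517 UMIs. Of these barcodes, 5970, 5355, 6618 and 8265 cells were used, with a median of 6432, 8200, 8427 and 5897 UMIs per cell. There was 1 library per treatment and so no replicate: values of 2 libraries are set side by side, no test between treatments was possible, and all 95% intervals cover counting error only.

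The question asked first was which cells the beads recovered under each treatment. Neutrophil-like cells made up 5.16% (4.61 to 5.75%) of control cells, 4.11% (3.59 to 4.67%) with phenformin, 3.16% (2.75 to 3.61%) with poly I:C and 4.11% (3.7 to 4.56%) in the combination. This order depends on the clustering: with each library clustered on its own, the control share was the lowest, not the highest, as given below. T or NK-like cells were 37.3% (36.2 to 38.3%) of the combination against 28.7% (27.5 to 29.8%) of control, 27.2% with phenformin and 30.3% with poly I:C. Monocyte or macrophage-like cells were 29.9% (28.7 to 31.1%) in control, 36.2% (34.9 to 37.5%) with phenformin, 35.3% (34.2 to 36.5%) with poly I:C and 32.03% (31.02 to 33.05%) in the combination. Dendritic-like cells were lower in both poly I:C-treated libraries, at 4.97% (4.46 to 5.52%) and 4.2% (3.78 to 4.65%) against 7.4% (6.75 to 8.1%) in control and 7.26% with phenformin. Control, phenformin, poly I:C and combination had 1.44%, 1.87%, 1.65% and 2.42% B or plasma-like cells. Tumour epithelial-like cells were 8.81%, 5.53%, 10.9% and 7.37%, and unnamed clusters 17.5%, 16.7%, 11.6% and 11.1%, in the same order. The largest control cluster was among those left unnamed and held 8.71%, 7.56%, 1.62% and 1.42%. Of unnamed control cells 50.2% had a C1qa UMI and 52.7% a Ccl24 UMI, both macrophage transcripts. The monocyte or macrophage-like shares may thus depend in part on what was left unnamed. The CD45 bead enrichment sets these shares in part, so they are not shares of the tumour.

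**Figure D1:**
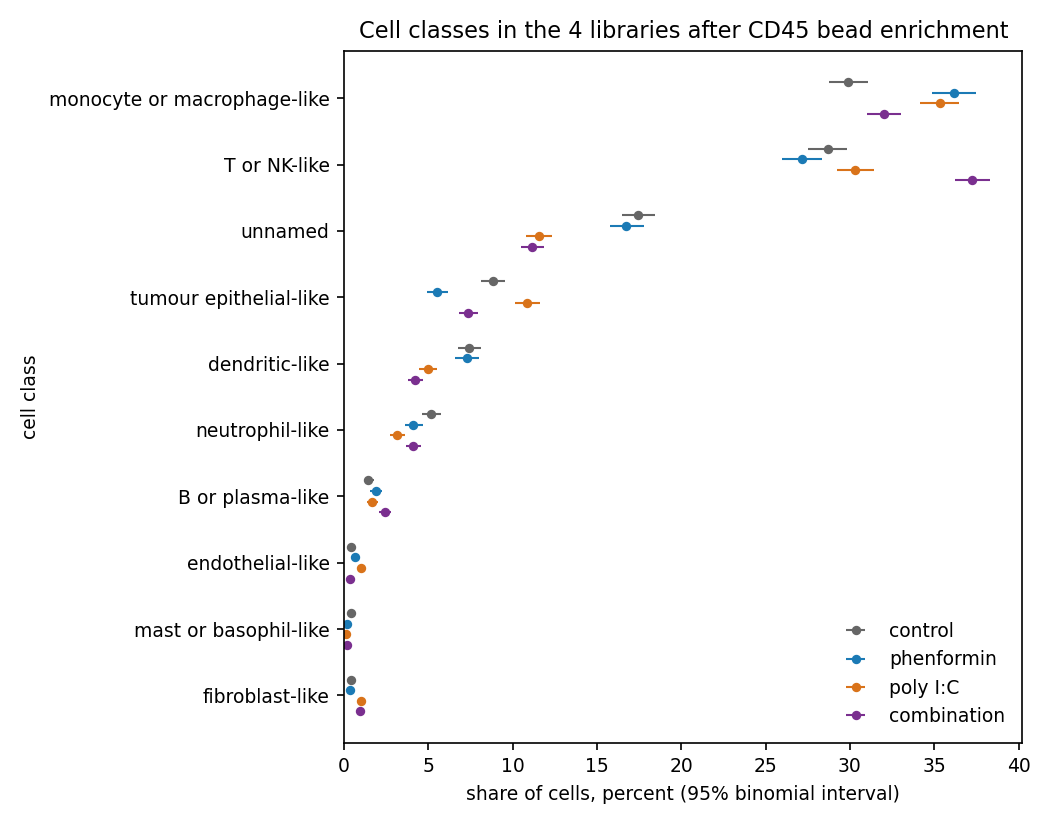
Share of cells in percent (horizontal axis) for each cell class (vertical axis) in the 4 libraries, with points for the share and bars for its exact 95% binomial interval. Neutrophil-like cells lay between 3.16% and 5.16%, and T or NK-like cells were highest in the combination at 37.3%.

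Different clusters made up some classes in the 4 libraries. A T cell cluster led by Lef1, Satb1, S1pr1 and Klf2, genes of naive T cells, held 402 combination cells and 22, 33 and 23 cells of control, phenformin and poly I:C. A cluster drawn mostly from 1 library can be that library, not a cell type. Of the monocyte or macrophage-like cells, control had most in the clusters led by Vcam1, Ccl8 and C1q genes (467 cells), by Thbs1, Vcan and Ly6c2 (401) and by Ccl24, Arg1 and Nos2 (351). The combination had most in the first of these (953) and in those led by Cd72, Slamf9 and Cxcl13 (397) and by Mmp12 and Trem2 (388). Dendritic-like cells of control, phenformin, poly I:C and combination lay in clusters led by Klk1 and Siglech (plasmacytoid-like; 173, 163, 159 and 179 cells), by Plet1, Cst3, Cd209a and Cd209e (conventional-like; 152, 150, 106 and 72) and by Ccl22, Fscn1 and Ccl17 (migratory-like; 117, 76, 64 and 96). A cluster led by Apoe, Vcam1 and Ccl8 was kept unnamed by a limit on doublet scores set after the data were seen, and held 0.704%, 0.317%, 3.22% and 2.2% of control, phenformin, poly I:C and combination cells.

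The neutrophil-like cluster was led by S100a9, S100a8, Retnlg, Camp, G0s2 and Cxcr2 and held 308 control, 220 phenformin, 209 poly I:C and 340 combination cells. Their summed counts were small, at 648892, 487499, 578182 and 837394 UMIs, with a median of 1768, 2050, 1927 and 1928 UMIs per cell. A pair of sub-clusters with a median UMI count over 2 times that of the class was led by monocyte genes (Ms4a4c, Ace, Vcan) or T cell genes (Nkg7, Cd3g, Icos), and is called mixed here. Mixed cells were 6.82%, 6.36%, 11.96% and 9.41% of the neutrophil-like cells of control, phenformin, poly I:C and combination but held 20.3%, 12.5%, 35.9% and 26.99% of the UMIs, so values without them are given where they differ. Summed Cd3d, Cd3e and Cd3g counts, of T cells, were 66.3, 20.5, 353 and 177 CPM in the class, and Apoe, a macrophage transcript, was 193, 283, 766 and 386 CPM. The neutrophil genes S100a8 and S100a9, calcium-binding alarmins, reached 11180, 18120, 19000 and 30030 CPM and 17080, 31030, 35210 and 62830 CPM. Some of the genes named below lie, in GRCm38 and on the GENCODE vM21 annotation, as follows: Isg15 (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), Rsad2 (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452), Cybb (ENSMUSG00000015340, chromosome X, 9435252 to 9487771), Camp (ENSMUSG00000038357, chromosome 9, 109847379 to 109849617), Ccl24 (ENSMUSG00000004814, chromosome 5, 135569937 to 135573049) and Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188).

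Phenformin alone was compared with control to ask how tumours under complex I inhibition differed without a TLR ligand. In neutrophil-like cells 12 of 2266 compared genes were at least 2-fold higher and 106 at least 2-fold lower with phenformin. Granule genes had 1 of 12 higher and 5 lower (median log2 -0.19, percentile 16.2), and a median of 0.12 without the cells holding 3 or more Camp plus Ngp UMIs. The antimicrobial peptide gene Camp had no phenformin UMI and a ratio of at most 0.0366 by the floor of 3 counts. The granule genes Ngp and Ltf were 0.0115-fold (0.000288 to 0.0652) and 0.217-fold (0.0889 to 0.463). These granule transcripts came from few cells: 2 control, 0 phenformin, 3 poly I:C and 9 combination cells held 3 or more Camp plus Ngp UMIs. The other lowest genes were Gzma (0.0391), Ctla4 (0.0986), Stmn1 (0.121), Mmp13 (0.138), Mmp12 (0.146), Pmepa1 (0.185) and Atp2a2 (0.213), where the values in parentheses are ratios. Gzma and Ctla4 are lymphocyte genes, and Cd3 counts were lower with phenformin as well. Without the mixed cells Gzma was 0.606-fold, Ctla4 0.303-fold, Stmn1 0.364-fold and Mmp13 2.12-fold, and with each library clustered on its own Stmn1 was 1.39-fold and Mmp13 1.24-fold. The highest were Chil3, a chitinase-like gene of the same granule list, at 4.07-fold (2.35 to 7.36), and Pla1a (3.55), Nars2 (2.79), Bcl2l15 (2.66), Sap30 (2.66), Klf10 (2.5), Hist1h1c (2.4), St3gal6 (2.26), Mt1 (2.16) and Manf (2.05).

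The type I interferon list had 1 of 36 higher and 5 lower (median log2 -0.17, percentile 19.1), and a median of 0.00 under TMM scaling. Ifit3 was 0.407-fold (0.187 to 0.817), Usp18 0.552-fold (0.32 to 0.924) and Isg15, an interferon-induced ubiquitin-like modifier, 1.04-fold (0.971 to 1.11). Usp18 was 1.22-fold in cells thinned to 1000 UMIs. The NF-kB and inflammatory cytokine list had 0 of 29 higher and 2 lower (median log2 0.00, percentile 76.3), the lower ones being Ptgs2 at 0.597-fold (0.517 to 0.687) and the chemokine Cxcl1 at 0.658-fold (0.548 to 0.788). With each library clustered on its own the median was 0.70, Ptgs2 1.87-fold and Cxcl1 3.69-fold. Il1b was 1.13-fold (1.07 to 1.18) and Tnf 1.09-fold (0.824 to 1.45). Cybb, which encodes the catalytic subunit of the phagocyte NADPH oxidase, was 0.642-fold (0.499 to 0.823). The oxidase list had 0 of 8 higher and 1 lower (median log2 -0.02, percentile 67.3). Nuclear complex I genes had 0 of 33 higher and 4 lower (median log2 -0.22, percentile 46.8), with Ndufb3 at 0.213-fold (0.0539 to 0.617). The mitochondrially encoded subunits had 1 of 7 higher and 0 lower (median log2 -0.07, percentile 50.5). The nuclear median was 0.02 with all variable genes used for clustering and 0.18 at a clustering resolution of 0.5. TMM scaling changed the split of 2-fold genes to 22 higher and 66 lower and the median of all genes from -0.18 to -0.03 log2, and without the mixed cells the counts were 8 and 53.

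The highest of the compared genes of monocyte or macrophage-like cells with phenformin were Saa3 at 3.6-fold (3.16 to 4.12), Ccl17 at 2.22-fold (2.02 to 2.44), F13a1 at 1.94-fold (1.81 to 2.08), Chil1 at 1.84-fold (1.71 to 1.98) and the lipid carrier Apoe at 1.77-fold (1.75 to 1.79). Mfge8, a bridging molecule for apoptotic cells, was 0.362-fold (0.321 to 0.409) and the monocyte chemokine receptor Ccr2 0.574-fold (0.539 to 0.611), followed by Fam129a (0.609), Tppp3 (0.663) and Rsad2 (0.682). The alternatively activated macrophage list had 4 of 14 higher and 0 lower (median log2 0.24, percentile 100), with Folr2 at 1.87-fold (1.66 to 2.12) and Il10 at 1.53-fold (1.3 to 1.81). The largest cluster of the class was that led by Ccl24, Arg1 and Nos2 (579 cells) with phenformin but that led by Vcam1, Ccl8 and C1q genes (467 cells) in control. In dendritic-like cells the chemokines Ccl24 (3.52) and Ccl17 (2.95) were highest, with Clec4n (2.22), Hilpda (2.23) and Cxcl10 (2.2), and Mfge8 (0.177), Ccl8 (0.337), Cd209e (0.372), C1qa (0.468) and Hist1h1b (0.456) lowest. Ccl24 was 0.769-fold with all variable genes used for clustering and Ccl8 1.21-fold with each library clustered on its own. The type I interferon list had 1 of 29 higher and 7 lower (median log2 -0.26, percentile 0). Highest in T or NK-like cells were Hspa1a (2.79), Ccl4 (2.25), Hspa1b (2.09), Apoe (2.03) and Hist1h4d (1.83), and lowest Nrp1 (0.45), Car2 (0.545), Ugcg (0.586), Ramp1 (0.564) and Tbc1d4 (0.573).

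Poly I:C alone was compared with control to ask how TLR activation without complex I inhibition differed. In neutrophil-like cells interferon-stimulated genes were lower, not higher, on day 4: the type I interferon list had 3 of 36 higher and 21 lower (median log2 -0.89, percentile 0). The antiviral genes Rsad2 and Ifih1 were 0.187-fold (0.161 to 0.217) and 0.196-fold (0.127 to 0.292), Slfn5 0.215-fold (0.145 to 0.309), Slfn4 0.239-fold (0.204 to 0.279), Isg15 0.538-fold (0.498 to 0.581) and the chemokine Cxcl10 0.567-fold (0.439 to 0.729). Without the mixed cells the median of this list was -0.80. Heat shock and immediate early genes, which respond to tissue dissociation, were lower too, with 0 of 14 higher and 9 lower (median log2 -0.79, percentile 0.02). Hspa1a was 0.0125-fold (0.00458 to 0.0275), Egr1 0.365-fold (0.322 to 0.413) and Atf3 0.397-fold (0.312 to 0.501). With each library clustered on its own this median was -0.31 and Hspa1a 1.35-fold. In contrast, 17 of 33 nuclear complex I genes were higher and 0 lower (median log2 0.65, percentile 100), with Ndufv3 at 3.66-fold (2.27 to 6.12) and Ndufs6 at 2.92-fold (1.57 to 5.7). Without the mixed cells this median was 0.62. Mitochondrially encoded complex I genes had 2 of 7 higher and 0 lower (median log2 0.12, percentile 57.7), and a median of -0.71 without the mixed cells but 0.51 with limits of 500 genes and 10% mitochondrial UMIs.

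The NF-kB list had 1 of 29 higher and 11 lower (median log2 -0.48, percentile 0.41), with Zfp36 at 0.244-fold (0.205 to 0.287), Ptgs2 at 0.251-fold (0.207 to 0.301) and the interleukin-1 receptor antagonist Il1rn at 0.269-fold (0.244 to 0.296). Il1b was 0.871-fold (0.829 to 0.915). This median was -0.23 without the mixed cells and 0.25 with each library clustered on its own, where Zfp36 was 0.379-fold, Ptgs2 0.605-fold and Il1rn 0.35-fold. Among the oxidase genes Cyba was 1.66-fold (1.46 to 1.89) and Ncf4 1.55-fold (1.3 to 1.85), and Cybb was 0.759-fold (0.606 to 0.949) but 1.23-fold with all variable genes used for clustering. The list had 2 of 8 higher and 0 lower (median log2 -0.13, percentile 46.6). Ncf4 was 0.901-fold with each library clustered on its own. The granule list had 6 of 12 higher and 1 lower (median log2 0.66, percentile 99.4), with Chil3 at 17.3-fold (10.8 to 29.7), Camp at 4.11-fold (3.32 to 5.12), Ltf at 3.09-fold (2.21 to 4.38) and Mmp8 at 2.65-fold (1.95 to 3.64). Its median was 0.84 without the mixed cells but -0.20 without the cells holding 3 or more Camp plus Ngp UMIs, where Ltf was 0.329-fold, and -0.33 with each library clustered on its own. MHC class I genes had 8 of 17 higher and 2 lower (median log2 0.41, percentile 98.1), led by H2-Q7 at 2.24-fold (1.83 to 2.75) and H2-T22 at 2.38-fold (1.28 to 4.63). Lymphocyte transcripts ranked among the highest: Cd3g (9.35), Cd8b1 (7.63), Ptprcap (7.11), Pdcd1 (6.56) and Nkg7 (4.73), beside Gzmb at 4.39-fold (2.72 to 7.36), with Cd3 counts at 353 CPM against 66.3. Without the mixed cells Cd3g was 0.838-fold, Ptprcap 0.698-fold, Pdcd1 0.698-fold, Nkg7 0.14-fold and Gzmb 0.465-fold. The other highest were Vcan, a monocyte gene, at 7.38-fold (3.31 to 19.4) and 4.19-fold without the mixed cells, and Acot9 (7.18), Pycard (5.2) and Nupr1 (5.49).

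The lowest genes were Hspa1b at 0.0115-fold (0.00236 to 0.0339), Ccl24 at 0.0259-fold (0.00527 to 0.0774), Mmp12 (0.0588), Hpgds (0.0591), Pecam1 (0.128), Col6a3 (0.152) and Hist1h1b (0.102). The collagenase Mmp13 had no UMI with poly I:C (ratio at most 0.0437). With each library clustered on its own Mmp12 was 1.19-fold and Hist1h1b 9.41-fold. Ccl24, a macrophage chemokine, was also lower in monocyte or macrophage-like cells, at 0.108-fold (0.105 to 0.111). Of 2648 compared genes 311 were at least 2-fold higher and 250 at least 2-fold lower. TMM scaling turned this split to 155 higher and 383 lower and moved the median of all genes from 0.12 to -0.07 log2, and without the mixed cells 158 were higher and 255 lower.

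Monocyte or macrophage-like cells had Apoe at 4.35-fold (4.31 to 4.4), Saa3 at 3.79-fold (3.34 to 4.33), the neutrophil chemoattractant Cxcl1 at 3.54-fold (3.11 to 4.03), Pf4 at 3.1-fold (2.97 to 3.25) and Ecm1 at 2.8-fold (2.64 to 2.97). Retnla was 0.169-fold (0.155 to 0.184), Ccr2 0.212-fold (0.196 to 0.23), Flt1 0.313-fold (0.284 to 0.345) and Thbs1 0.348-fold (0.337 to 0.36). The myeloid-derived suppressor cell list had 4 of 10 higher and 1 lower (median log2 0.31, percentile 99.95), with Wfdc17 at 2.25-fold (2.18 to 2.33) and the arginase gene Arg1 at 0.462-fold (0.448 to 0.476). The largest cluster of the class was that led by Vcam1, Ccl8 and C1q genes in both libraries (467 and 920 cells), followed by classical monocytes in control (401) and by the Ccl24 and Arg1 cluster with poly I:C (541). In dendritic-like cells the type I interferon list was higher, with 11 of 29 higher and 0 lower (median log2 0.36, percentile 100), led by Rsad2 at 3.42-fold (2.22 to 5.39), Slfn1 at 3.2-fold (2.4 to 4.29) and Cxcl10 at 2.88-fold (2.28 to 3.65). In cells thinned to 1000 UMIs its median was 0.07, with Slfn1 at 0.331-fold. The highest dendritic genes were S100a9 (77.8), S100a8 (47.2), Cxcl3 (27.4), Clec4e (11.3) and Ccl3 (10). S100a9 UMIs were found in 8.81% of these cells with poly I:C and 2.49% in control, against 2.74% and 1.93% of T or NK-like cells (median depth 8571, 8618, 4698 and 4467 UMIs). Lowest were the lectins Cd209e (0.0214) and Cd209a (0.139), with Mfge8 (0.0593), Aldh1a2 (0.152) and H2-M2 (0.266).

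In T or NK-like cells cytotoxic genes were higher with poly I:C, with 8 of 16 higher and 3 lower (median log2 0.51, percentile 100) of the lymphocyte cytotoxicity list. Ccl5 was 3.36-fold (3.3 to 3.41), Ccl3 3.49-fold (3.01 to 4.07), Ccl4 3.06-fold (2.84 to 3.29) and Gzmk 2.86-fold (2.34 to 3.51). The T cell exhaustion list had 4 of 7 higher and 0 lower (median log2 0.49, percentile 100), with Havcr2 at 1.71-fold (1.61 to 1.82) and Lag3 at 1.64-fold (1.53 to 1.75) and a median of 0.16 in cells thinned to 1000 UMIs. The regulatory T cell list had 0 of 6 higher and 3 lower (median log2 -0.71, percentile 0), with Foxp3 at 0.344-fold (0.30 to 0.392) and Il2ra at 0.41-fold (0.385 to 0.437). The CD8 T cell cluster was 971 of the class's cells with poly I:C and 393 in control, and the Foxp3 cluster 151 and 313. Other named genes were Apoe (4.46) and Tff1 (2.97) at the high end and Scd2 (0.323), Maf (0.367), Il1rl1 (0.349) and Tcf7 (0.36) at the low end. Apoe is a macrophage transcript and had a UMI in 55.1% of these cells with poly I:C and 19.6% in control.

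The combination was compared with control for the joint effect of complex I inhibition and TLR activation, the pairing that the study's title ties to cytotoxic neutrophils. In neutrophil-like cells interferon and NF-kB genes were lower and a few oxidase and granule genes higher. The type I interferon list had 6 of 36 higher and 16 lower (median log2 -0.53, percentile 0), with Rsad2 at 0.222-fold (0.197 to 0.25), Ifih1 at 0.252-fold (0.182 to 0.345) and Isg15 at 0.688-fold (0.646 to 0.733), but Cxcl10 was 1.61-fold (1.35 to 1.92), or 0.925-fold with each library clustered on its own. The NF-kB list had 0 of 29 higher and 15 lower (median log2 -0.61, percentile 0.01), with Il1rn at 0.227-fold (0.207 to 0.247), the chemokine Ccl4 at 0.251-fold (0.239 to 0.264) and Ptgs2 at 0.258-fold (0.22 to 0.302). The tumour-associated neutrophil list had 0 of 15 higher and 7 lower (median log2 -0.53, percentile 1.03), with Cd274, which encodes PD-L1, at 0.466-fold (0.43 to 0.505). Both medians reversed sign when each library was clustered on its own, to 0.07 and 0.97, with Ccl4 at 1.17-fold and Cd274 at 1.05-fold. There 109 control cells were named neutrophil-like in place of 308. The cause was not tested. The dissociation and immediate early list had 0 of 14 higher and 5 lower (median log2 -0.50, percentile 1.7).

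Of the effector genes of the death ligand list, with 4 of 7 higher and 1 lower (median log2 0.76, percentile 99.8), Tnf was 0.377-fold (0.268 to 0.525), the inducible nitric oxide synthase gene Nos2 1.77-fold (1.15 to 2.8), Ltb 1.76-fold (1.36 to 2.31), Gzmb 1.97-fold (1.19 to 3.39) and Fasl 1.78-fold (0.816 to 4.2). Tnfsf10, which encodes TRAIL, had 4, 1, 3 and 1 UMIs, too few for a ratio. Nos2 was 0.934-fold with all variable genes used for clustering, Tnf 3.41-fold with each library clustered on its own and Gzmb 0.705-fold without the mixed cells. Beside these stood Cd3 counts of 177 CPM against 66.3 in control, and without the cells holding a Cd3 UMI the list's median was -0.16. Of the NADPH oxidase genes Ncf4 was 1.7-fold (1.45 to 1.99), Cyba 1.56-fold (1.38 to 1.76), Rac2 1.4-fold (1.18 to 1.67), Cybb 0.945-fold (0.781 to 1.14), Ncf1 0.941-fold (0.756 to 1.17) and Rac1 1.08-fold (0.925 to 1.27). The list had 2 of 8 higher and 0 lower (median log2 0.03, percentile 66.2). Hvcn1 and BC017643 were 1.55-fold (0.415 to 7.03) and 0.775-fold (0.421 to 1.43). Rac2 was 0.766-fold with each library clustered on its own. Il1b was 0.987-fold (0.945 to 1.03), Arg1 0.957-fold (0.481 to 1.93) and the chemokine receptor Cxcr2 0.788-fold (0.714 to 0.87).

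The secondary and tertiary granule list had 7 of 12 higher and 1 lower (median log2 1.32, percentile 100). Chil3 was 24.6-fold (15.4 to 41.8), Camp 16.4-fold (13.5 to 20.1), Ngp 11.5-fold (9.52 to 14) and Ltf 4.32-fold (3.18 to 5.98). Camp UMIs were found in 3.24% of combination and 0.32% of control neutrophil-like cells, against 0.1% of T or NK-like cells of the combination (median depth 1928, 1768 and 4116 UMIs). Without the 9 combination and 2 control cells holding 3 or more Camp plus Ngp UMIs the median was -0.02, with Ltf at 0.969-fold, and without the mixed cells 0.79. Other highest genes were the neutrophil surface gene Ly6g at 9.3-fold (4.32 to 23.8), the protease inhibitor Serpinb1a at 17.6-fold (5.76 to 87.3), Stfa2 (7.23), Stfa3 (7.7), Ifitm6 (5.02) and Hmgn2 (5.33). The azurophil protease Prtn3 had no control UMI and was at least 23.2-fold higher, with UMIs in 0.59% of combination cells. The lowest were Ccl24 at 0.00596-fold (0.00015 to 0.0338), Col6a3 at 0.0301-fold (0.00805 to 0.0794), Hspa1a at 0.0318-fold (0.0197 to 0.0486), Hspa1b (0.132), Mmp12 (0.059), Mmp13 (0.0604), Mrc1 (0.0969) and Slc15a2 (0.185). Ccl24 and the mannose receptor gene Mrc1 are macrophage transcripts, and Ccl24 was 0.0368-fold (0.0353 to 0.0383) in monocyte or macrophage-like cells. Mrc1 was 2.35-fold with each library clustered on its own.

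Metabolic lists moved apart in the neutrophil-like cells. The 7 mitochondrially encoded complex I genes had 0 of 7 higher and 4 lower (median log2 -0.69, percentile 1.29), with mt-Nd4l at 0.452-fold (0.273 to 0.735) and mt-Nd1 at 0.546-fold (0.485 to 0.614), and -1.02 without the mixed cells but -0.28 with limits of 500 genes and 10% mitochondrial UMIs. The median share of all mitochondrial UMIs per cell was not lower, at 0.434% in the combination and 0.37% in control. Nuclear complex I genes had 5 of 33 higher and 0 lower (median log2 0.25, percentile 98.3), led by Ndufa6 at 3.1-fold (2.03 to 4.87), and 0.03 without the mixed cells. Glycolysis genes had 4 of 19 higher and 4 lower (median log2 0.25, percentile 95.1). Gpi1 was 2.2-fold (1.82 to 2.68) and Gapdh 2.01-fold (1.82 to 2.21), while the hexokinases Hk1 and Hk2 were 0.481-fold (0.33 to 0.695) and 0.616-fold (0.491 to 0.771), the last 2.95-fold with each library clustered on its own. Of 2498 compared genes 109 were at least 2-fold higher and 189 at least 2-fold lower, as under TMM scaling (109 and 189). Without the mixed cells the counts were 125 and 174.

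**Figure D2:**
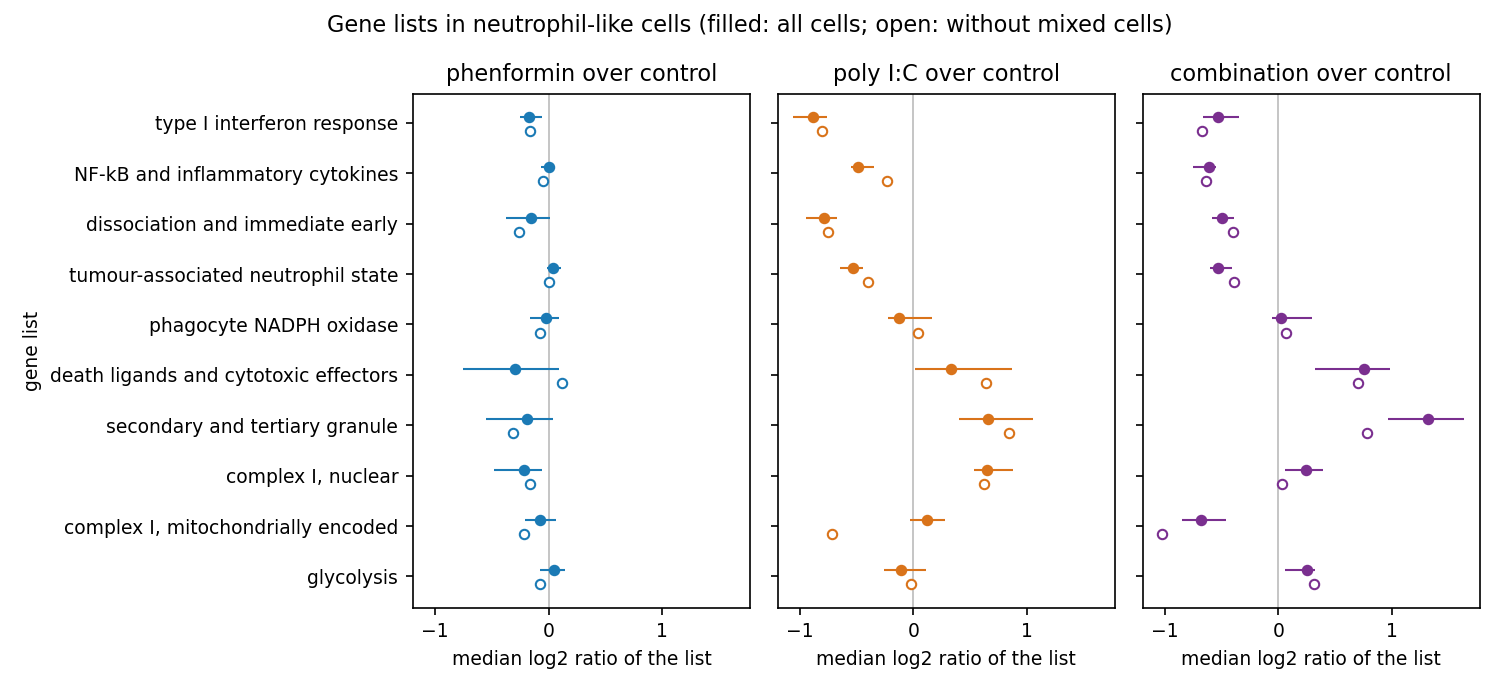
Median log2 ratio to control (horizontal axis) of 10 gene lists (vertical axis) in neutrophil-like cells of the phenformin, poly I:C and combination libraries, with filled points and 95% counting intervals for all cells and open points without the mixed cells. The type I interferon median was -0.89 with poly I:C and -0.53 in the combination, and -0.80 and -0.67 without the mixed cells.

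In monocyte or macrophage-like cells of the combination the eosinophil chemoattractant Ccl24 was the lowest gene, followed by Flt1 (0.125), Plet1 (0.163), Thbs1 (0.285) and Fn1 (0.312). The alternatively activated list had 3 of 14 higher and 6 lower (median log2 -0.41, percentile 0), with Mgl2 at 0.347-fold (0.323 to 0.374) and Arg1 at 0.445-fold (0.431 to 0.459) but Folr2 at 3.0-fold (2.68 to 3.37). With each library clustered on its own this median was -0.20. The highest were Saa3 at 6.42-fold (5.66 to 7.31), the T cell chemokine Ccl5 at 5.47-fold (5.36 to 5.59), the B cell chemokine Cxcl13 at 4.88-fold (4.27 to 5.59) and Apoe at 2.94-fold (2.91 to 2.96). Proliferation genes had 7 of 11 higher and 0 lower (median log2 0.75, percentile 100), with Tk1 at 2.49-fold (2.08 to 2.98) and Birc5 at 2.19-fold (1.94 to 2.47). Glycolysis had 0 of 17 higher and 2 lower (median log2 -0.24, percentile 0.52), with Pgk1 at 0.496-fold (0.443 to 0.555). Mitochondrially encoded complex I had 0 of 7 higher and 2 lower (median log2 -0.45, percentile 0.1). The proliferation median was -0.07 with each library clustered on its own and 0.12 with the clusters weighted alike in both libraries. In this class the type I interferon list had 4 of 29 higher and 3 lower (median log2 0.06, percentile 95.6). After the Vcam1 and Ccl8 cluster (953 cells) the class's largest clusters were those led by Cd72, Slamf9 and Cxcl13 (397) and by Mmp12 and Trem2 (388) in the combination, but classical monocytes (401) and the Ccl24 cluster (351) in control.

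Dendritic-like cells of the combination had S100a9 (78.3), S100a8 (31.4), Apoe (6.22), C1qb (4.65) and Ccl5 (4.37) at the high end, of which the S100a genes mark neutrophils and Apoe and C1qb macrophages, and Cd209e (0.0412), Ccl24 (0.0711), Mgl2 (0.142), Mfge8 (0.21) and Cd209a (0.226) at the low end. Cd209a and Cd209e lead the conventional-like cluster, with 72 combination and 152 control cells. In the dendritic-like class the type I interferon list had 10 of 29 higher and 2 lower (median log2 0.04, percentile 68.4), and a median of -0.17 in cells thinned to 1000 UMIs. T or NK-like cells had Apoe (3.69), Ccl5 (2.46), C1qa (2.52), Isg20 (2.44) and Ifi27l2a (2.22) highest and Scd2 (0.329), Il18rap (0.409), Itgb3 (0.427), Il2ra (0.439) and Tcf7 (0.425) lowest. Their regulatory T cell list had 0 of 6 higher and 3 lower (median log2 -0.49, percentile 0.03) and their lymphocyte cytotoxicity list 5 of 16 higher and 0 lower (median log2 0.17, percentile 99.8). Mean over cells in place of summed counts gave -0.09 for the latter, and equal cluster weights -0.18 for the former.

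**Figure D3:**
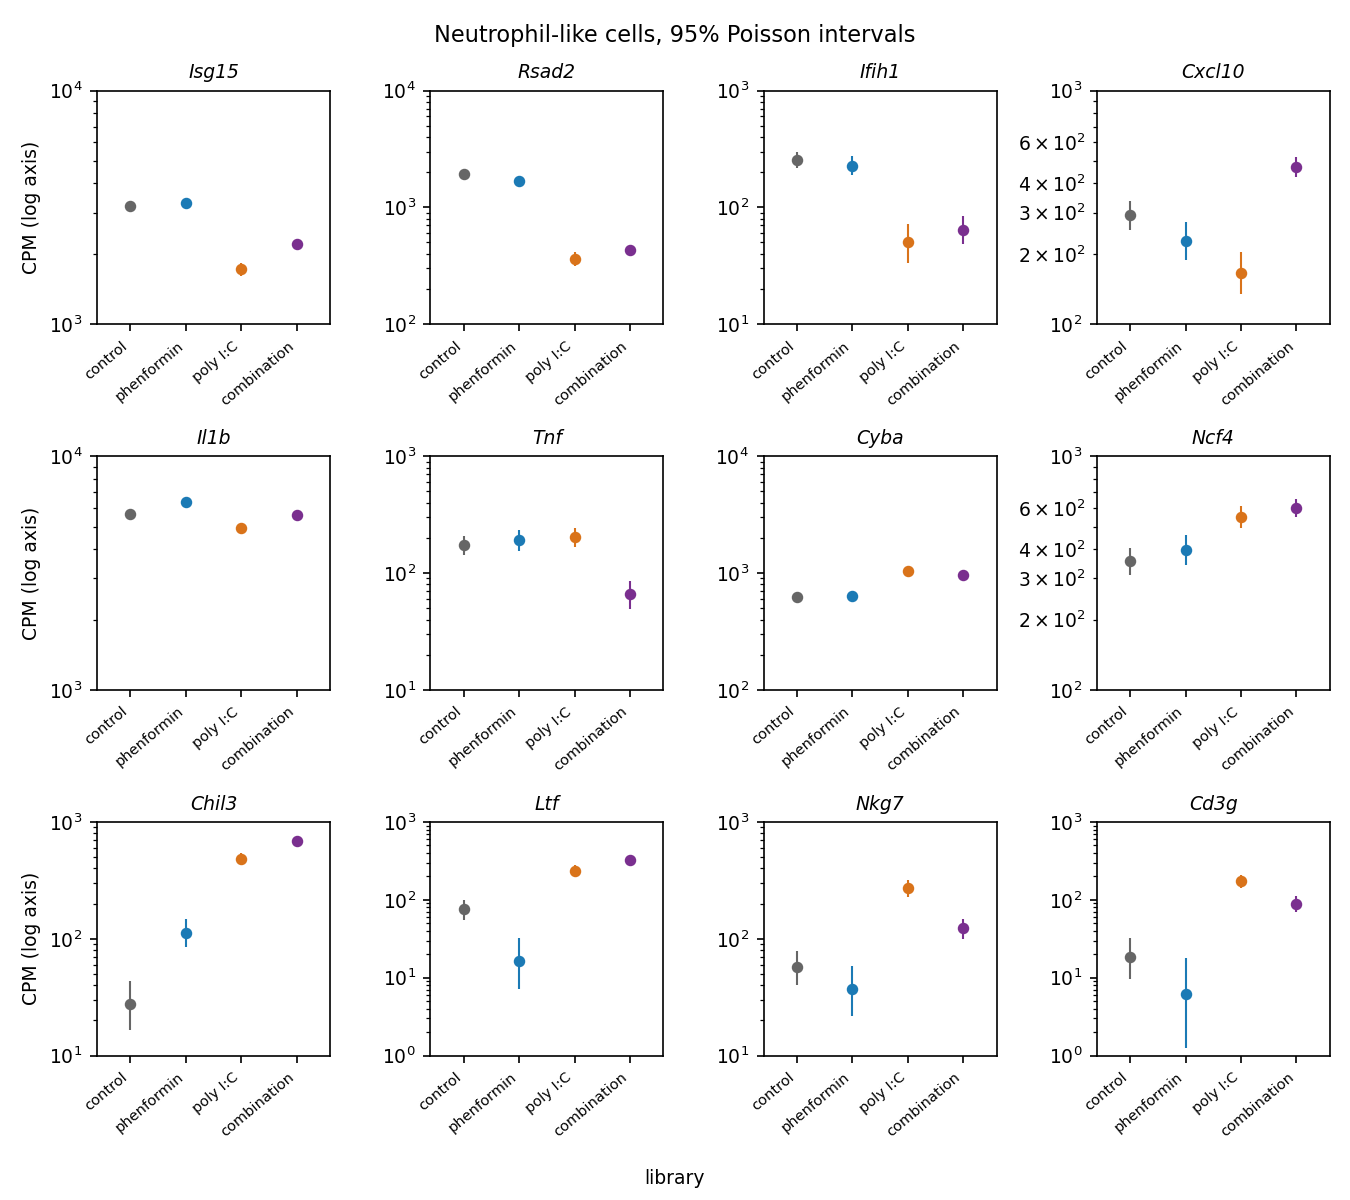
CPM (vertical, logarithmic axis) of 12 genes in neutrophil-like cells of the 4 libraries (horizontal axis), with exact 95% Poisson intervals. Rsad2 was 1931, 1668, 362 and 429 CPM and Cyba 621, 634, 1031 and 969.7 CPM in control, phenformin, poly I:C and combination.

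The combination was compared with poly I:C alone to see what phenformin added. In neutrophil-like cells the interferon list was higher than with poly I:C alone, with 11 of 36 higher and 0 lower (median log2 0.30, percentile 100), 0.20 without the mixed cells and 0.13 in cells thinned to 1000 UMIs. Cxcl10 was 2.83-fold (2.26 to 3.58), Ifit3 2.4-fold (1.38 to 4.38) and Isg15 1.28-fold (1.18 to 1.38). Tnf was 0.325-fold (0.231 to 0.451), Il1a 0.51-fold (0.388 to 0.669) and Il1b 1.13-fold (1.08 to 1.19). The NF-kB list had 0 of 29 higher and 5 lower (median log2 -0.14, percentile 6.29) but a median of 0.06 under TMM scaling. Both complex I lists were lower, the nuclear with 0 of 33 higher and 13 lower (median log2 -0.48, percentile 0.02) and the mitochondrially encoded with 0 of 7 higher and 5 lower (median log2 -0.79, percentile 0.03). Ndufa5 was 0.329-fold (0.138 to 0.729), Ndufb3 0.485-fold (0.282 to 0.823) and mt-Nd5 0.425-fold (0.336 to 0.536), and without the mixed cells the medians were -0.51 and -0.33. At a clustering resolution of 0.5 the nuclear median was -0.20. Glycolysis genes had 3 of 19 higher and 0 lower (median log2 0.23, percentile 99.3), with the lactate exporter Slc16a3 at 1.61-fold (1.38 to 1.88) and the glucose transporter Slc2a1 at 1.6-fold (1.3 to 1.97).

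Of the oxidase list, with 1 of 8 higher and 0 lower (median log2 0.09, percentile 68.1), Rac2 was 1.53-fold (1.27 to 1.85), Cybb 1.24-fold (1.0 to 1.54) and Ncf4 1.09-fold (0.947 to 1.26). Nos2 was 1.09-fold (0.74 to 1.62), Fasl 1.99-fold (0.857 to 5.13) and Cxcr2 1.09-fold (0.975 to 1.22). Cybb was 0.868-fold with each library clustered on its own. The granule list had 4 of 12 higher and 0 lower (median log2 0.46, percentile 99.98). The highest genes were Hspa1b (11.5), Gzma (8.86), Stfa3 (5.83), Ngp (5.01), Camp (3.99), Ly6g (3.87), Serpinb1a (3.35) and Ifitm6 (3.21), with Hist1h1b at 10.6-fold (3.4 to 53.2) over 3 UMIs and Prtn3 at 62.1-fold (10.9 to 2481) over 1, of which Prtn3 came from 0.59% of combination cells. The granule median was 0.00 without the mixed cells and 0.24 without the cells holding 3 or more Camp plus Ngp UMIs, where Camp was 0.63-fold, Ngp 1.91-fold and Prtn3 0.736-fold. Gzma was 0.909-fold and Serpinb1a 0.779-fold without the mixed cells, and with each library clustered on its own Hspa1b was 0.672-fold and Hist1h1b 0.779-fold. Among the lowest were Vcan (0.105), Cd8b1 (0.183), Spp1 (0.254), Ccr7 (0.209), Sdc3 (0.224), H2-Ab1 (0.297), Cd74 (0.301), Lmna (0.254) and Sdc4 (0.288), among them monocyte, T cell and antigen presentation genes. The mixed cells held 35.9% of UMIs with poly I:C and 26.99% in the combination. Without them Vcan was 0.404-fold, H2-Ab1 1.12-fold and Cd74 0.857-fold. Of 2537 compared genes 46 were at least 2-fold higher and 100 lower. TMM scaling turned the split to 97 and 47 and moved the median of all genes from -0.13 to 0.06 log2, and without the mixed cells it was 55 and 43.

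Monocyte or macrophage-like cells had higher Cxcl13, at 16.7-fold (14.1 to 20), Retnla at 3.29-fold (3.03 to 3.59), Slamf9 at 2.43-fold (2.3 to 2.56), Pou2f2 at 2.61-fold (2.38 to 2.86) and Ccl5 at 2.15-fold (2.12 to 2.17) than with poly I:C alone. Lower were Cxcl1 at 0.35-fold (0.319 to 0.385), Cxcl2 at 0.412-fold (0.404 to 0.42) and Ccl24 at 0.341-fold (0.325 to 0.356), with Inhba (0.356) and Upp1 (0.388). Cxcl1 and Cxcl2 attract neutrophils. The alternatively activated list had 2 of 14 higher and 4 lower (median log2 -0.34, percentile 0). Hypoxia had 0 of 11 higher and 2 lower (median log2 -0.26, percentile 0), with Hilpda at 0.518-fold (0.503 to 0.535). Proliferation had 9 of 11 higher and 0 lower (median log2 0.67, percentile 100). The last median was 0.07 with each library clustered on its own and 0.18 with equal cluster weights, under which the hypoxia median was -0.08. Cluster sizes differed as well: the Ccl24 and Arg1 cluster held 541 cells with poly I:C and 210 in the combination, and the Cd72, Slamf9 and Cxcl13 cluster 123 and 397. In dendritic-like cells H2-M2 (5.42), Ccl5 (3.29), Ms4a7 (3.04) and C1qb (2.75) were highest beside Retnla at 204-fold (36.1 to 8082) over 1 poly I:C UMI, and Cxcl2 (0.191), Cxcl3 (0.243), Ccl3 (0.307), Ccl17 (0.336) and Plet1 (0.382) lowest. C1qb was 0.967-fold with each library clustered on its own. T or NK-like cells had Klf2 (2.41), Areg (2.28), Maf (2.13), Gzma (1.98) and Rgs10 (1.94) highest and Ccl3 (0.408), Hist1h4d (0.576), Mt2 (0.598), St6galnac3 (0.631) and Hist1h1e (0.646) lowest. Klf2 led the naive T cell cluster, which held 402 combination and 23 poly I:C cells.

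The combination was compared with phenformin alone to see what poly I:C added. Neutrophil-like cells had lower interferon genes, with 7 of 36 higher and 16 lower (median log2 -0.30, percentile 0.73), -0.53 without the mixed cells and -0.11 with no limit on low values. Rsad2 was 0.257-fold (0.226 to 0.291), Ifih1 0.283-fold (0.201 to 0.396) and Isg15 0.664-fold (0.621 to 0.71), but Ifit3 was 3.12-fold (1.62 to 6.59) and Cxcl10 2.07-fold (1.67 to 2.57). The NF-kB list had 1 of 29 higher and 18 lower (median log2 -0.88, percentile 0), with Il1rn at 0.232-fold (0.211 to 0.254), Ccl4 at 0.238-fold (0.226 to 0.25) and Tnf at 0.344-fold (0.242 to 0.486). Oxidase genes had 2 of 8 higher and 0 lower (median log2 0.54, percentile 95.2), with Cyba at 1.53-fold (1.34 to 1.75), Ncf4 at 1.51-fold (1.28 to 1.79) and Cybb at 1.47-fold (1.16 to 1.88), or 0.975-fold without the cells holding 3 or more Camp plus Ngp UMIs. Nuclear complex I genes had 11 of 33 higher and 0 lower (median log2 0.55, percentile 99.5). Mitochondrially encoded ones had 0 of 7 higher and 4 lower (median log2 -0.62, percentile 1.91), with mt-Nd3 at 0.339-fold (0.234 to 0.485). The oxidase median was 0.09 in cells thinned to 1000 UMIs, the nuclear median 0.08 without the mixed cells and the mitochondrial median -0.02 with limits of 500 genes and 10% mitochondrial UMIs. Effector genes of lymphocytes stood higher, Gzma at 44.8-fold (7.81 to 1793) over 1 phenformin UMI, Gzmb at 6.52-fold (2.63 to 20.9) and Fasl at 4.46-fold (1.35 to 23.2), beside Cd3g at 14.6-fold (4.79 to 72.2). In cells thinned to 1000 UMIs Gzmb was 0.867-fold and Fasl 1.24-fold, and without the mixed cells Gzma was 2.09-fold.

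The granule list had 7 of 12 higher and 0 lower (median log2 1.002, percentile 100), and a median of -0.24 without the cells holding 3 or more Camp plus Ngp UMIs. Camp, without a phenformin UMI, was at least 448-fold higher, Ngp 1002-fold (179.6 to 39600) over 1 UMI and Ltf 19.9-fold (9.94 to 46.5), and Prtn3 was at least 17.5-fold higher. The other highest genes were Serpinb1a (39.6), Stfa3 (9.84), Ifitm6 (9.31) and Ctla2a (7.57) and the lowest Ccl24 (0.0121), Col6a3 (0.0395), Cd36 (0.0597), Hspa1a (0.12), Hspa1b (0.165), Cass4 (0.174), Slc15a2 (0.198) and Tgm2 (0.239). Ctla2a was 0.698-fold without the mixed cells. Of 2311 compared genes 298 were at least 2-fold higher and 165 lower. Under TMM scaling the split was 203 and 251, with the median of all genes at 0.04 in place of 0.19 log2, and without the mixed cells 180 and 126.

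In monocyte or macrophage-like cells the alternatively activated list had 1 of 14 higher and 8 lower (median log2 -0.79, percentile 0), with Ccl24 at 0.0334-fold (0.0321 to 0.0348), Ccl17 at 0.0883-fold (0.076 to 0.102), Plet1 (0.106), Flt1 (0.117) and Edn1 (0.176) lowest and Ccl5 (3.67), Cxcl13 (3.51), Rcan1 (2.48), Slamf9 (2.43) and Cd72 (2.41) highest. Glycolysis had 0 of 17 higher and 3 lower (median log2 -0.43, percentile 0). Hypoxia had 0 of 11 higher and 4 lower (median log2 -0.38, percentile 0.04), with Ndrg1 at 0.434-fold (0.413 to 0.455). Proliferation had 9 of 11 higher and 0 lower (median log2 0.76, percentile 100). The type I interferon list had 4 of 29 higher and 0 lower (median log2 0.24, percentile 100), with Irf7 at 2.0-fold (1.94 to 2.06). Equal cluster weights brought the proliferation median to 0.04 and clustering each library on its own to 0.22. With equal weights the glycolysis median was -0.20. The Ccl24 and Arg1 cluster held 579 cells with phenformin and 210 in the combination. Interferon genes were higher in dendritic-like cells too, with 14 of 29 higher and 3 lower (median log2 0.48, percentile 100). Highest there were S100a9 (301), S100a8 (108), C1qb (9.8), Apoe (9.56) and C1qa (8.81), and lowest Ccl24 (0.0202), Mgl2 (0.107), Ccl17 (0.22), Cd209a (0.253) and Mt2 (0.301). S100a9 UMIs lay in 4.61% of these cells in the combination and 1.54% with phenformin. In every comparison S100a8, S100a9, Apoe and C1q transcripts of dendritic-like or T or NK-like cells may stem from mixed droplets or free RNA. T or NK-like cells had the interferon list at 6 of 18 higher and 0 lower (median log2 0.22, percentile 100), the regulatory T cell list at 0 of 6 higher and 2 lower (median log2 -0.38, percentile 0.02) or -0.09 with equal cluster weights, Plac8 (2.29), Ifi27l2a (2.08), Irf7 (2.05), C1qa (1.99) and Spp1 (1.97) highest and Hspa1b (0.418), Il1rl1 (0.484), Foxp3 (0.488), Il2ra (0.489) and Hspa1a (0.493) lowest.

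**Figure D4:**
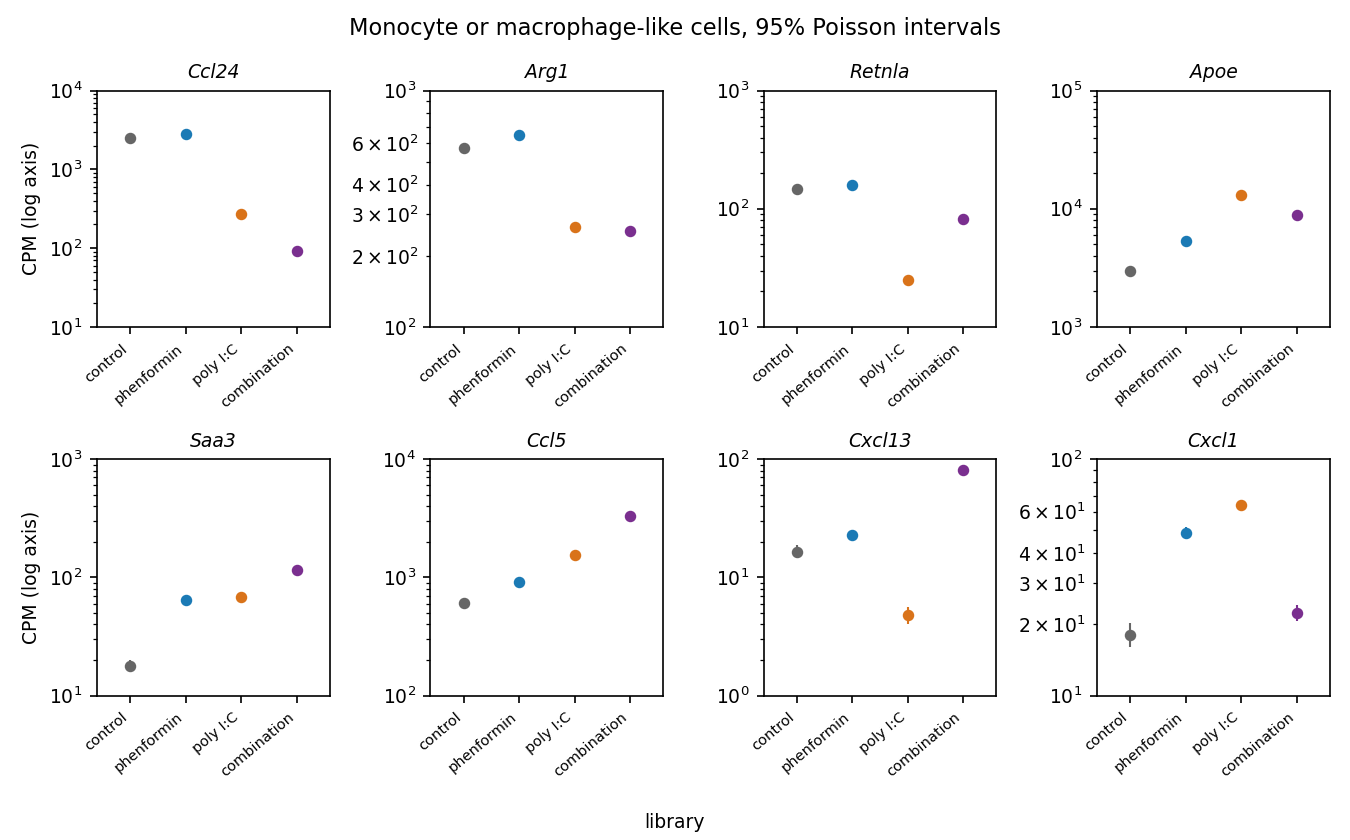
CPM (vertical, logarithmic axis) of 8 genes in monocyte or macrophage-like cells of the 4 libraries (horizontal axis), with exact 95% Poisson intervals, most of them narrower than the points. Ccl24 was 2532, 2787, 274 and 93.2 CPM and Cxcl13 16.5, 22.9, 4.8 and 80.3 CPM in control, phenformin, poly I:C and combination.

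Counts in the other classes are given for phenformin, poly I:C and combination against control, then for the combination against poly I:C and against phenformin. In monocyte or macrophage-like cells 2, 17, 23, 6 and 17 genes were at least 2-fold higher and 1, 20, 37, 15 and 42 lower. In dendritic-like cells 6, 34, 54, 19 and 61 genes were at least 2-fold higher and 8, 27, 35, 17 and 26 lower. In T or NK-like cells 4, 11, 9, 3 and 3 genes were at least 2-fold higher and 1, 35, 14, 2 and 5 lower. TMM scaling moved the higher share of these genes in some comparisons. In monocyte or macrophage-like cells it gave 3 and 0 for phenformin against control, 29 and 11 for poly I:C against control and 5 and 22 for the combination against poly I:C. In dendritic-like cells it gave 15 and 21 for the combination against poly I:C and 47 and 42 for the combination against phenformin. In T or NK-like cells it gave 19 and 18 for poly I:C against control, 16 and 6 for the combination against control and 8 and 1 for the combination against phenformin.

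The 2 by 2 layout also gives the combination beyond the sum of the single treatments, as log2 of combination over control minus the log2 values of poly I:C and of phenformin over control. In neutrophil-like cells the type I interferon median was 0.47 (percentile 100; 0.44 without the mixed cells). The genes furthest above the sum were Camp (7.10), Ngp (7.02), Gzma (5.68), Hist1h1b (4.25) and Prtn3 (4.06) (phenformin UMIs 0, 1, 1, 6 and 0). Among those furthest below were Sars (-3.03), Vcan (-2.79), Pla1a (-2.35) and Bcl2l15 (-2.07). Without the cells holding 3 or more Camp plus Ngp UMIs Camp was -0.44, Ngp 0.17 and Prtn3 -0.10, and without the mixed cells Gzma was 0.20 and Hist1h1b -0.04. The Camp, Ngp, Gzma and Prtn3 values, with 0 or 1 phenformin UMI, depend on the constant added to each CPM. In monocyte or macrophage-like cells Cxcl13 (2.75), Pou2f2 (1.91), Retnla (1.44), Slamf9 (1.38) and Hspa1b (1.31) lay above the sum and the neutrophil chemoattractants Cxcl1 (-2.55) and Cxcl2 (-1.85), with Plet1 (-2.05), Inhba (-2.04) and Ccl17 (-1.90), below it. The alternatively activated list's median was -0.57. In dendritic-like cells Mfge8 (3.75), Retnla (3.55), H2-M2 (3.02), C1qb (2.42) and C1qc (2.38) were above and Ccl17 (-3.09), Ccl24 (-3.08), Cxcl2 (-2.94), Cxcl3 (-2.04) and Hilpda (-2.01) below. With all variable genes used for clustering the dendritic Ccl24 value was 0.02. In T or NK-like cells Tmem64 (1.47), Gzma (1.32), Klf2 (1.24), Maf (1.21) and Klf3 (1.11) were above and Ccl3 (-1.86), Ccl4 (-1.62), Hist1h4d (-1.59), Tff1 (-1.26) and Apoe (-1.20) below, with the regulatory T cell list at 0.28 and the lymphocyte cytotoxicity list at -0.32. Hspa1a and Hspa1b, Ifit3 and Ifit3b, the Stfa genes and the H2-Q genes have near-identical copies, so the values of their single members are uncertain.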

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

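The limits that picked the lists below (a percentile of at most 0.1 or at least 99.9 and a median of at least 0.3 log2 either way, with the tumour class and the values beyond the single treatments left out) and the 3 patterns weighed were chosen after the data were seen, while the bounds of the tests were set before their values were computed, with 2 exceptions named below. Each list's median lay on opposite sides of 0 in different cell classes of the same pair of libraries, and the difference was not tested. For poly I:C over control the type I interferon median was -0.89 in neutrophil-like and 0.36 in dendritic-like cells, where it was 0.07 in cells thinned to 1000 UMIs. For the combination over poly I:C the hypoxia median was -0.30 in dendritic-like and 0.37 in neutrophil-like cells. For the combination over phenformin the regulatory T cell median was -0.38 in T or NK-like cells (-0.09 with equal cluster weights), 0.65 in dendritic-like cells and 1.66 in neutrophil-like cells, and for phenformin over control the lymphocyte cytotoxicity median was -0.72 in neutrophil-like and 0.54 in monocyte or macrophage-like cells. The last 2 lists are named for T or NK cells. Ccl5 of the last, at 609 CPM (control) and 907 CPM (phenformin) in monocyte or macrophage-like cells, is not specific to lymphocytes.

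Granule genes were higher in neutrophil-like cells of the combination than of control. Free RNA of other cells is argued against, since Camp plus Ngp reached 0.178 CPM in T or NK-like cells of that library, or 0.00369% of the 4811 CPM in its neutrophil-like cells. A small granule-rich subset accounts for most of the pattern: without the cells holding 3 or more Camp plus Ngp UMIs (9 in the combination, or 2.65% with an interval of 1.22 to 4.97%, and 2 in control, or 0.65% with 0.08 to 2.33%) the median of the other 10 list members was -0.022 in place of 0.77. Deeper cells cannot be told apart from a true difference: with every cell thinned to 1000 UMIs the list's median was 0.50 in place of 1.32, which met the bound set for depth as the cause, but its counting interval of 0.10 to 0.86 did not lie below that bound, and use of the interval was chosen after the value was seen. A treatment effect on immature, granule-rich neutrophils stays open and was not tested, because each treatment has 1 library.

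T and NK cell genes were higher in neutrophil-like cells of the poly I:C library than of control. Cd3 counts in these cells were 14.4% of the level in T or NK-like cells of the same library, and 8 lymphocyte genes reached a median of 0.792 times the level that these Cd3 counts bring, near what T or NK cell RNA in the same droplets gives. Of the Cd3 UMIs 93.6% lay in 11 cells that held 17.9% of the UMIs, a spread that doublets give and free RNA does not. Together the tests leave doublets or other mixed droplets with T cells as the likely source, which Scrublet calls at 0.02% in this library did not remove. Cytotoxic genes expressed by neutrophils themselves were not excluded for single genes, such as Gzmc at 2.24 times the expected level.

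The naive T, B and non-classical monocyte clusters were larger in the combination library, at 4.86%, 2.19% and 3.23% of cells, than in the others, at up to 0.616%, 1.48% and 2.70%, a small difference for the last. Globin was 0.632 CPM in the combination, or 0.102 times the highest other library (6.22 CPM, phenformin). This cannot decide on more blood in the sample, since CD45 beads select against red cells. Shallower cells as the whole cause are argued against for the naive T cluster, tested alone: among cells of 3000 UMIs or more its share was 2.21% in the combination against 0.390% at most elsewhere, a ratio of 5.67. Lymph node tissue in the sample cannot be told apart from a treatment effect, because the marker Ccl21a had 2 UMIs in the combination and 0 in the other libraries, at or under the floor of 3 counts, a limit applied to this test after its counts were seen. A treatment effect stays open and untested.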

How the results depend on the processing

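The alternatives that removed cells over a Scrublet score of 0.2, left out marker, list and leading genes from the clustering, joined unnamed clusters to their best class, gave clusters equal weight, or left out neutrophil-like cells with Cd3 UMIs, with 3 or more Camp plus Ngp UMIs or in mixed sub-clusters were chosen after the data were seen. The type I interferon median of neutrophil-like cells kept its sign under every alternative run for poly I:C over control (-1.09 to -0.70), the combination over control (-0.67 to -0.43), the combination over poly I:C (0.13 to 0.49), the combination over phenformin (-0.65 to -0.11) and the combination beyond the single treatments (0.39 to 0.72). For phenformin over control it ranged from -0.24 to 0.00, reaching 0.00 under TMM scaling. Of 1419 list medians under an alternative 1020 stayed inside their counting interval, 378 left it with the same sign and 21 reversed, and of 5684 gene values 4110 stayed, 1504 left their interval and 70 reversed. Counts of 2-fold genes stayed within 1.5 times in 508 of 730 cases, and class shares inside their interval in 268 of 324. Values that reversed, and the neutrophil-like counts, interferon medians and shares that moved further than this, follow by alternative, with the ratio or log2 value in parentheses after each gene. The cause was not tested for any of them.

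With cells over a Scrublet score of 0.2 removed, counts of 2-fold neutrophil genes were 207 higher for poly I:C over control and 62 lower for the combination over poly I:C. List medians were 0.22 for type I interferon response in neutrophil-like cells (combination over poly I:C). In neutrophil-like cells Gzmb (0.921, combination over control), Mmp13 (2.51, phenformin over control) and Nkg7 (0.859, poly I:C over control) reversed. With TMM scaling, counts of 2-fold neutrophil genes were 155 higher and 383 lower for poly I:C over control, 97 higher and 47 lower for the combination over poly I:C, 22 higher and 66 lower for phenformin over control and 251 lower for the combination over phenformin. Medians of lists were then 0.059 for NF-kB and inflammatory cytokines and 0.49 for type I interferon response in neutrophil-like cells (combination over poly I:C) and 0.00 for type I interferon response in neutrophil-like cells (phenformin over control). With all variable genes used for clustering, counts of 2-fold neutrophil genes were 493 higher for poly I:C over control, 190 higher for the combination over control and 41 higher and 65 lower for phenformin over control. The lists' medians were here 0.023 for complex I, nuclear in neutrophil-like cells (phenformin over control). In dendritic-like cells Ccl24 (0.023, combination beyond single treatments, and 0.769, phenformin over control) reversed. In neutrophil-like cells Cybb (1.23, poly I:C over control) and Nos2 (0.934, combination over control) reversed. So did Cybb (0.993) and Hist1h1b (0.668, both combination over poly I:C). With each cell thinned to 1000 UMIs, counts of 2-fold neutrophil genes were 108 higher for poly I:C over control, 133 higher and 87 lower for the combination over phenformin, 5 higher and 35 lower for phenformin over control and 21 lower for the combination over poly I:C. Among the lists, medians were -0.06 for lymphocyte cytotoxicity in T or NK-like cells (combination over control), -0.17 for type I interferon response in dendritic-like cells (combination over control) and 0.13 for type I interferon response in neutrophil-like cells (combination over poly I:C). In dendritic-like cells Ccl8 (1.2, phenformin over control) and Slfn1 (0.331, poly I:C over control) reversed. In neutrophil-like cells Gzmb (0.867, combination over phenformin) and Usp18 (1.22, phenformin over control) reversed. With each library clustered on its own, counts of 2-fold neutrophil genes were 691 higher for poly I:C over control, 313 higher for the combination over control, 185 higher for phenformin over control and 234 lower for the combination over poly I:C. Of the gene lists, medians were -0.003 for type I interferon response in dendritic-like cells (combination over control), -0.068 for proliferation in monocyte or macrophage-like cells (combination over control), 0.25 for NF-kB and inflammatory cytokines, -0.33 for secondary and tertiary granule, 1.15 for tumour-associated neutrophil state and -1.09 for type I interferon response in neutrophil-like cells (poly I:C over control), 0.046 for NF-kB and inflammatory cytokines and 0.46 for type I interferon response in neutrophil-like cells (combination over poly I:C), 0.065 for NF-kB and inflammatory cytokines and 0.97 for tumour-associated neutrophil state in neutrophil-like cells (combination over control) and 0.72 for type I interferon response in neutrophil-like cells (combination beyond single treatments). In dendritic-like cells C1qb (0.967, combination over poly I:C) and Ccl8 (1.21, phenformin over control) reversed. Ccl4 (1.17), Cd274 (1.05), Cxcl10 (0.925), Hk2 (2.95), Mrc1 (2.35), Rac2 (0.766) and Tnf (3.41) reversed in neutrophil-like cells for the combination over control. Cxcl1 (3.69), Mmp13 (1.24), Ptgs2 (1.87) and Stmn1 (1.39) did so for phenformin over control. Cybb (1.51), Hist1h1b (9.41), Hspa1a (1.35), Mmp12 (1.19) and Ncf4 (0.901) did so for poly I:C over control. Cybb (0.868), Hist1h1b (0.779) and Hspa1b (0.672) did so for the combination over poly I:C. Hist1h1b (-1.21) did so for the combination beyond the single treatments. Neutrophil-like cells were 1.83% of control cells in place of 5.16%. With no doublets removed, counts of 2-fold neutrophil genes were 204 higher for poly I:C over control and 198 higher for the combination over phenformin. With the neutrophil-like cells with a Cd3 UMI left out, counts of 2-fold neutrophil genes were 143 higher for poly I:C over control, 196 higher for the combination over phenformin and 58 lower for the combination over poly I:C. Medians of lists were then -0.16 for death ligands and cytotoxic effectors in neutrophil-like cells (combination over control) and -0.71 for type I interferon response in neutrophil-like cells (poly I:C over control). In neutrophil-like cells Ctla2a (0.463, combination over phenformin) and Gzmb (0.551, combination over control) reversed. Gzmb (0.873), Ltf (0.409), Nkg7 (0.298), Pdcd1 (0.655) and Ptprcap (0.655) did so for poly I:C over control. With the mixed cells left out, counts of 2-fold neutrophil genes were 158 higher for poly I:C over control, 180 higher for the combination over phenformin, 43 lower for the combination over poly I:C and 53 lower for phenformin over control. The lists' medians were here 0.20 for type I interferon response in neutrophil-like cells (combination over poly I:C) and -0.67 for type I interferon response in neutrophil-like cells (combination over control). Cd3g (0.838), Gzmb (0.465), Nkg7 (0.14), Pdcd1 (0.698) and Ptprcap (0.698) reversed in neutrophil-like cells for poly I:C over control. Ctla2a (0.698) reversed in neutrophil-like cells for the combination over phenformin. Cybb (0.996), Gzma (0.909), H2-Ab1 (1.12) and Serpinb1a (0.779) reversed in neutrophil-like cells for the combination over poly I:C. In neutrophil-like cells Gzmb (0.705, combination over control), Hist1h1b (-0.036, combination beyond single treatments) and Mmp13 (2.12, phenformin over control) reversed. With genes of 20 CPM or more compared, counts of 2-fold neutrophil genes were 74 higher for the combination over poly I:C. With Leiden resolution 0.5, counts of 2-fold neutrophil genes were 262 higher for the combination over control, 49 higher and 56 lower for phenformin over control and 42 lower for the combination over poly I:C. Of the gene lists, medians were 0.18 for complex I, nuclear in neutrophil-like cells (phenformin over control). In dendritic-like cells Ccl24 (0.89, combination beyond single treatments, and 0.769, phenformin over control) reversed. In neutrophil-like cells Cybb (1.27, poly I:C over control) and Nos2 (0.952, combination over control) reversed. So did Cybb (0.982) and Hspa1b (0.689, both combination over poly I:C). With clustering without marker, list and leading genes, counts of 2-fold neutrophil genes were 177 higher for the combination over phenformin and 69 lower for phenformin over control. List medians were 0.012 for complex I, nuclear in neutrophil-like cells (phenformin over control). Nos2 (0.955) reversed in neutrophil-like cells for the combination over control. With the cells with 3 or more Camp plus Ngp UMIs left out, neutrophil-like secondary and tertiary granule medians were -0.20 (poly I:C over control), -0.022 (combination over control) and -0.24 (combination over phenformin). The type I interferon median was 0.45 (combination over poly I:C). Camp (-0.44) and Prtn3 (-0.10) reversed in neutrophil-like cells for the combination beyond the single treatments. Camp (0.63), Cybb (0.916) and Prtn3 (0.736) reversed in neutrophil-like cells for the combination over poly I:C. In neutrophil-like cells Cybb (0.975, combination over phenformin) and Ltf (0.329, poly I:C over control, and 0.969, combination over control) reversed. With the mean over cells in place of the sum, the lists' medians were here -0.092 for lymphocyte cytotoxicity in T or NK-like cells (combination over control), -0.039 for type I interferon response in dendritic-like cells (combination over control) and -0.70 for type I interferon response in neutrophil-like cells (poly I:C over control). With list members of 100 CPM or more, among the lists, medians were -0.65 for type I interferon response in neutrophil-like cells (combination over phenformin).

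The alternative without clusters held over 60% by 1 library gave values for T or NK-like cells alone, since no cluster of the other compared classes met it. No paired analysis was possible because each treatment has 1 library. Depth limits the neutrophil-like class most, with 35 control, 23 phenformin, 9 poly I:C and 22 combination cells under 1000 UMIs left out by thinning.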

Other observations

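The values in this part were chosen after the data were seen. Tumour epithelial-like cells, which CD45 beads select against, numbered 526 in control, 296 with phenformin, 719 with poly I:C and 609 in the combination. Their interferon genes were lower in both poly I:C-treated libraries than in control: the type I interferon list had 0 of 25 higher and 14 lower (median log2 -0.55, percentile 0) with poly I:C and 0 of 25 higher and 15 lower (median log2 -0.59, percentile 0) in the combination. With list members of 100 CPM or more these medians were -0.16 and -0.21. The interferon-gamma and GTPase list had 1 of 14 higher and 5 lower (median log2 -0.42, percentile 0.04) and 0 of 14 higher and 12 lower (median log2 -0.80, percentile 0). The GTPase gene Irgm2 was at 0.40-fold (0.364 to 0.439) and 0.337-fold (0.302 to 0.375). The ubiquitin ligase gene Dtx3l was at 0.384-fold (0.351 to 0.42) and 0.418-fold (0.38 to 0.459). Parp14 was at 0.452-fold (0.41 to 0.498) in the combination. The iron-binding Lcn2 was 1.88-fold (1.83 to 1.93) with phenformin over control and 3.27-fold (3.18 to 3.36) in the combination over poly I:C. Itln1 was 2.64-fold (2.32 to 3.02) and 7.92-fold (6.79 to 9.27). The milk protein gene Csn3 was 0.132-fold (0.112 to 0.155) with poly I:C over control and 7.98-fold (6.82 to 9.39) in the combination over poly I:C. A Csn3 UMI was found in 4.56%, 8.11%, 2.36% and 6.24% of these cells in control, phenformin, poly I:C and combination. Macrophage transcripts stood higher in these cells with poly I:C, Apoe at 19.01-fold (16.9 to 21.4) and C1qa at 11.7-fold (10.0 to 13.8). This stood beside 13040 CPM of Apoe in monocyte or macrophage-like cells against 2995 CPM in control. In the combination Apoe, C1qa and the lymphocyte genes Gzmb and Nkg7 were at 159, 113, 24.6 and 30.9 CPM in tumour epithelial-like cells, higher than the 21.8, 11.9, 3.27 and 8.24 CPM of control.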
